A study of Arabidopsis thaliana with 24 samples.

How the data were processed

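Poly-A RNA sequencing was carried out on root samples of Arabidopsis thaliana seedlings, aged 5 days post germination. The seedlings were wild type (Col-0, WT) or vamp714, a mutant line labelled GABI, which is the name of a T-DNA insertion collection. VAMP714 encodes an R-SNARE, a protein of vesicle fusion. Seedlings had spent 0, 3, 9 or 24 h on half-strength medium with 150 mM NaCl, and each of the 8 groups held 3 libraries. No sample analysed here is labelled as untreated at 3, 9 or 24 h, so the effect of salt and the effect of time after transfer are confounded. Sample titles call every WT library mock, while the sample characteristics give 150 mM NaCl at 3, 9 and 24 h, and the characteristics were followed. Whether the libraries of a group came from separate cultures is not given in the sources used here, so the p-values measure only the spread between these samples. The protocol names a directional and a non-directional library option, so the strand setting is unknown and reads from overlapping genes on opposite strands cannot be assigned.

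The submitters' processing notes name CASAVA for base calling and TAIR10 as the genome build. The aligner and the counting tool are not given in the sources used here. The deposited table lists a raw read count for each gene and library. It also lists an FPKM value for each gene and library, which the authors scaled by the gene length in the table and by a size for each library. The deposited columns of the authors' own comparisons hold a log2 fold change and an adjusted p-value for each gene, made with a tool that is not named. Another deposited file pairs genes with GO terms, an identifier rather than a measured unit. The KEGG file was not used. All 48 count and FPKM columns were assigned to samples by title. The table holds 38299 genes, of which 38286 matched the reference annotation by locus, each with equal start and end coordinates.

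Every test started from the raw counts. FPKM values served only to check the library totals. The listed counts were 91.12% (vamp714 0 h replicate 3) to 112.2% (WT 3 h replicate 1) of the totals that the FPKM values imply. The FPKM values were therefore not scaled by the plain count totals. Library totals ran from 16696442 to 29943561 counts. Genes were kept with filterByExpr of edgeR (minimum count 10, minimum total count 15), which left 21227 genes holding 99.96% of the counts. Normalization was by TMM. A quasi-likelihood model was fitted in edgeR 4.0.16 under R 4.3.3 to all 24 libraries with a mean for each of the 8 groups. The biological coefficient of variation was 15.5%. Genes with a Benjamini-Hochberg adjusted p under 0.05 in a contrast are called. Standard errors are the size of the log2 fold change divided by the square root of F, and are left out where that size is under 0.01. The contrasts were each later time against 0 h within a genotype, WT at 24 h against 3 h, vamp714 against WT at each time and over the mean of the 4 times, and the difference between genotypes in the change from 0 h.

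For genes with no count in a group, the fold is a lower bound from a floor of 3 counts over that group. For genes with 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only.

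The 21 lists of genes held 417 loci, of which 403 were tested. The lists covered ABA and osmotic stress, ion transport, NADPH oxidases, ROS-scavenging enzymes, auxin transport, auxin response, auxin synthesis and signalling, SNARE and endosomal trafficking, the circadian clock, cell division, hypoxia, iron deficiency, jasmonate, ethylene, ER protein folding and suberin. The remaining lists held markers of the Casparian strip and endodermis, root hairs, xylem and phloem, the root cap and stem cell niche, and shoot photosynthesis. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over 315 tests. Camera with an estimated correlation and fry were run beside it. Fry passed 132 of the 315 tests, among them 79 of the 110 camera calls at the preset correlation. Of 110 list calls at the preset correlation, 11 held with an estimated correlation: ABA and osmotic stress in all 7 comparisons between times, hypoxia in WT at 9 h and 24 h, and iron deficiency between genotypes at 3 h and over the mean of the times. GO terms with 10 to 500 tested genes were tested with a 1-sided hypergeometric test for called genes, higher and lower apart, against the 20307 tested genes that had a GO term.

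The comparisons, tests, lists, the rule for naming genes and the alternative settings were chosen before the data were examined, except where a later choice is stated. The rule took VAMP714 in every library. In each contrast it took the 5 largest increases and 5 largest decreases among called genes with a mean of at least 1 CPM and groups whose libraries do not overlap, a separation that chance gives 10% of the time for 3 against 3. It took up to 4 called members of each list, or, where none was called, up to 2 with the highest expression. It also took SOS1, HKT1, NHX1, RBOHC, RBOHD, RBOHF, PIN2, AUX1, P5CS1 and RD29A in every genotype and salt contrast, and the 4 protein-coding genes on each side of VAMP714. 1 more gene of this set is not reported here. Not all genes allowed by the rule are named.

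The alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, a stricter filter (1 CPM in 3 libraries), a block for replicate number, a fit of only the compared groups, a further threshold of a 2-fold change, and omission of each library in turn. After the data were seen, 2 more were added: removal of WT 24 h replicate 2 with vamp714 24 h replicate 3, which stood apart in the principal components, and a test of the genotype by time difference without the 0 h libraries. Counts of called genes were compared with those of other splits of the same libraries. The pipeline was tested on simulated data, in which 200 of 21100 genes were changed between 2 groups of 3 libraries. It recovered 115 of them (57.5%) with 3 false calls. Recovery was 23.9% at 1.5-fold, 62.7% at 2-fold and 86.4% at 4-fold, so most changes under 2-fold between the genotypes at 1 time would be missed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.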

Results

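Gene expression was measured by poly-A RNA sequencing in roots of WT and vamp714 Arabidopsis seedlings at 0, 3, 9 and 24 h on medium with 150 mM NaCl. The 24 libraries, 3 in each of 8 groups, held 16696442 to 29943561 counts each. The first principal component of log2 CPM held 48.9% of the variance and the second held 22.9%. Changes are log2 fold changes ± the standard error of the edgeR fit, with n = 3 libraries per group unless another n is given. Positions refer to the TAIR10 build.

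VAMP714 (AT5G22360, chromosome 5, 7404004 to 7405883) had 52.1 ± 4.08 CPM (SD, n = 3) in WT and 8.89 ± 1.88 CPM in vamp714 at 0 h. It was lower in vamp714 at every time, by -2.55 ± 0.113 at 0 h (edgeR adjusted p = 2.71e-12), -3.05 ± 0.117 at 3 h, -2.96 ± 0.115 at 9 h and -2.42 ± 0.112 at 24 h. Transcripts of the gene therefore remained countable in all 12 mutant libraries. The neighbours of VAMP714 were not called in the mean over the 4 times. RIN1 had -0.007, AT5G22340 0.06 ± 0.0696, ELM1 0.04 ± 0.043, QQT1 -0.05 ± 0.0614 and AT5G22400 0.07 ± 0.0732. AT5G22355 had -0.51 ± 0.147 (edgeR adjusted p = 0.111, or 0.0459 without vamp714 0 h replicate 1), and AT5G22390 had -1.43 ± 0.637 (adjusted p = 0.382), but -0.43 without WT 24 h replicate 2 and -2.24 without vamp714 9 h replicate 1. NAC090, with 27 counts in all libraries together, was not tested.

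**Figure D1:**
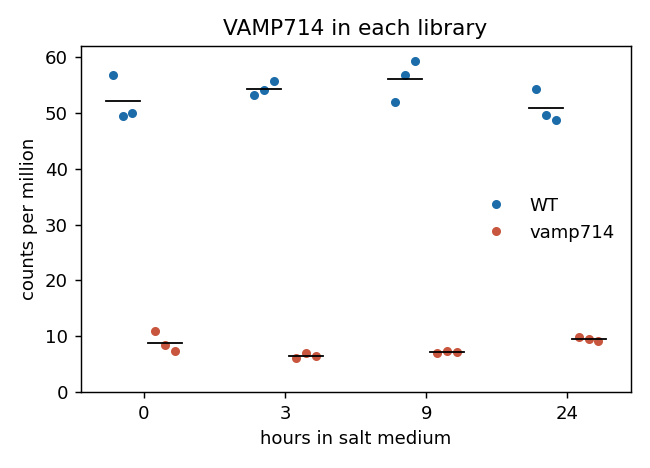
CPM of VAMP714 (vertical axis) by hours in salt medium (horizontal axis) in WT and vamp714, with 1 point per library and a line at each group mean. WT libraries sit between 48.7 and 59.3 CPM and vamp714 libraries between 6.12 and 10.97 CPM.

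The comparison of WT roots at 3 h with 0 h asks what changed early on salt medium. Stress genes of the abscisic acid (ABA) pathway rose together. RD29A, a gene induced by drought and cold, went from 350 ± 23.6 CPM to 8820 ± 649 CPM (SD, n = 3), a change of 4.66 ± 0.146. P5CS1, which makes the enzyme that limits proline synthesis, rose by 3.38 ± 0.112. COR15A, which encodes a protein that protects chloroplast membranes, had 1 count at 0 h and rose 17000-fold (95% counting interval 3040 to 670000). COR15B was at least 1840-fold higher, GASA3 at least 1300-fold, the transcription factor gene NAC019 at least 623-fold and AT4G01985 at least 1610-fold. The terpene synthase gene TPS13 was at least 456-fold lower, the ethylene synthesis gene ACS5 at least 129-fold lower and the extensin gene EXT11 at least 121-fold lower. All 36 ABA and osmotic-stress genes rose, also when adjusted over the list alone, with a median of 3.84 (camera adjusted p = 1.4e-69, and adjusted p = 0.00067 with an estimated correlation). RD20, a caleosin gene, was 1160-fold higher (207 to 45800).

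At 3 h in WT, 14 of 35 ion transport genes rose and 14 fell. Among them, the anion channel gene SLAH1 fell by 6.83 ± 0.486, the nitrate transporter gene NPF7.3 fell by 5.17 ± 0.223, the chloride transporter gene NPF2.4 fell by 5.14 ± 0.267 and the potassium channel gene SKOR fell by 3.89 ± 0.228. HKT1, which retrieves sodium from the xylem, fell by 1.90 ± 0.354, and the sodium/proton antiporter gene of the plasma membrane, SOS1, fell by 0.70 ± 0.133. The vacuolar antiporter gene NHX1 rose by 0.93 ± 0.112. Among 8 NADPH oxidase genes, which make superoxide outside the cell, 4 rose and 3 fell. RBOHC rose by 1.27 ± 0.155, RBOHD by 0.98 ± 0.276 and RBOHF by 1.27 ± 0.128, while RBOHG fell by 2.23 ± 0.226 and RBOHB fell by 1.24 ± 0.176. Of 32 ROS-scavenging enzyme genes, 7 rose and 14 fell; the ascorbate peroxidase gene APX2 rose by 6.16 ± 0.382 and the catalase gene CAT1 by 1.43 ± 0.0891. The auxin uptake carrier genes AUX1 at -1.64 ± 0.118, LAX1 at -2.35 ± 0.247 and LAX3 at -2.41 ± 0.143 were among the 9 of 21 auxin transport genes that fell, while 6 rose. The efflux carrier gene PIN2 (-0.07 ± 0.23) was not called. Auxin-responsive genes went both ways (12 of 37 rose, 10 fell; IAA14 -2.68 ± 0.243, GH3.2 -2.40 ± 0.35), as did auxin synthesis and signalling genes (10 of 29 rose, 12 fell; CYP79B3 -4.26 ± 0.198). SNARE and endosomal trafficking genes did too, with 7 of 32 higher and 12 lower (11 lower when adjusted over the list alone). None of these 7 lists passed the camera test (adjusted p from 0.401 to 0.925). Median and mean differed in sign for ion transport (0.06 and -0.46), ROS scavenging (-0.34 and 0.06) and SNARE genes (-0.09 and 0.04), and the auxin-responsive list had a median of -0.02 with a test direction upward.

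Fermentation genes rose in WT at 3 h, with ADH1, alcohol dehydrogenase, at 7.56 ± 0.221, SUS1, sucrose synthase, at 4.83 ± 0.141 and PDC1, pyruvate decarboxylase, at 3.07 ± 0.137. Of 10 hypoxia-responsive genes, 7 rose and 2 fell (camera adjusted p = 3.89e-06, and adjusted p = 0.103 with an estimated correlation). Suberin genes, which build a barrier in root cell walls, rose in 13 of 17 cases, among them the acyltransferase gene GPAT7 (4.05 ± 0.299) and the regulator MYB41 (3.29 ± 0.196), with a camera adjusted p = 0.000333 and an adjusted p = 0.705 with an estimated correlation. Clock genes rose in 16 of 22 cases and fell in 4, with COR27 at 4.50 ± 0.214 and FKF1 at 3.79 ± 0.158 (camera adjusted p = 2.58e-08, and adjusted p = 0.0698 with an estimated correlation). Iron-deficiency genes fell in 9 of 10 cases, with the regulator FIT at -2.07 ± 0.187 and the copper transporter gene COPT2 at -2.65 ± 0.321 (camera adjusted p = 0.00566, and adjusted p = 0.464 with an estimated correlation). Root hair genes fell in 7 of 8 cases, or 8 when adjusted over the list alone, with the wall protein gene PRP3 at -7.49 ± 1.12 and the expansin gene EXPA7 at -4.58 ± 0.653 (camera adjusted p = 0.0455, and adjusted p = 0.761 with an estimated correlation). Cell division genes fell in 16 of 19 cases, or 17 when adjusted over the list alone, with the cyclin gene CYCB1-2 at -1.74 ± 0.138 and TSO2, for ribonucleotide reductase, at -1.93 ± 0.198 (camera adjusted p = 0.00024, and adjusted p = 0.464 with an estimated correlation). Shoot photosynthesis genes, markers of green tissue, fell in 17 of 22 cases, with LHCB6 at -2.80 ± 0.37 (camera adjusted p = 0.00382, and adjusted p = 0.785 with an estimated correlation).

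The remaining lists did not pass the camera test at 3 h in WT. Of 16 jasmonate genes 6 rose and 1 fell, with the repressor gene JAZ1 at 2.58 ± 0.173. Of 12 ethylene genes 6 rose and 3 fell, with the synthesis genes ACS6 at 4.58 ± 0.429 and ACS7 at 3.65 ± 0.44. ER protein-folding genes rose in 2 of 7 cases and fell in 5. Casparian strip and endodermis genes fell in 5 of 9 cases, with CASP2, a scaffold of the Casparian strip, at -2.53 ± 0.26. Xylem and phloem genes rose in 7 of 12 cases and fell in 1, and root cap and stem cell niche genes rose in 2 of 9 and fell in 6. Over all genes, 13667 of 21227 were called at 3 h, 6381 higher and 7286 lower. The GO term response to hypoxia held 150 higher genes of 260 (78.7 expected, adjusted p = 2.77e-17), and structural constituent of ribosome held 177 lower genes of 276 (95.8 expected, adjusted p = 4.65e-20).

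**Figure D2:**
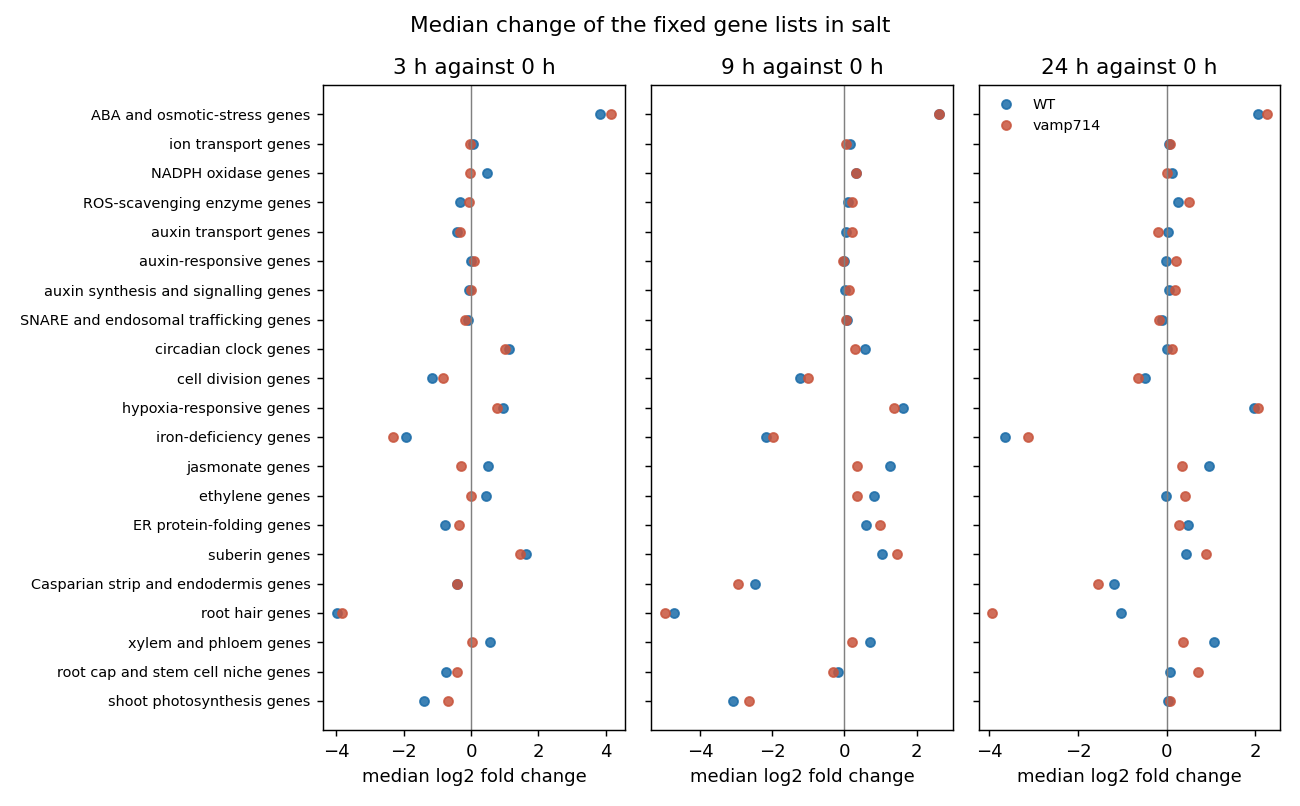
Median log2 fold change (horizontal axis) of the 21 fixed gene lists (vertical axis) at 3, 9 and 24 h against 0 h, with 1 point for WT and 1 for vamp714. ABA and osmotic-stress genes have the highest median in every panel for WT, at 3.84, 2.60 and 2.05, and root hair genes in WT lie at -3.98, -4.72 and -1.04.

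At 9 h in WT, ABA and osmotic-stress genes were still higher than at 0 h: 34 of 36 rose and 1 fell (median 2.60, camera adjusted p = 1.32e-37, and adjusted p = 0.0081 with an estimated correlation). RD20 was 400-fold higher (71.4 to 15800), P5CS1 had risen by 2.75 ± 0.109 and RD29A by 1.99 ± 0.13. The lipid transfer protein gene LTP4 was at least 1190-fold higher and AT5G07310 at least 547-fold higher, while EXT6 was at least 219-fold lower and RHS13, a root-hair-specific gene, was 1310-fold lower (234 to 51700). Of the ion transport genes, SLAH1 was at -8.66 ± 0.559 and SKOR at -5.52 ± 0.253, whereas the nitrate transporter gene NPF7.2 rose by 5.33 ± 0.477. HKT1 fell by 4.51 ± 0.433, NHX1 had risen by 0.42 ± 0.112, and SOS1 was not called (0.02 ± 0.13). RBOHD rose by 1.76 ± 0.28, RBOHF by 0.77 ± 0.127 and APX2 by 5.93 ± 0.384, and RBOHG fell by 3.096 ± 0.235. RBOHC was called at 0.42 ± 0.153, but its adjusted p was 0.0695 without WT 0 h replicate 2, 0.0648 without WT 0 h replicate 3 and 0.163 without WT 9 h replicate 1. AUX1 fell by 0.45 ± 0.114, YUC9, an auxin synthesis gene, rose by 2.51 ± 0.212, IAA17 fell by 2.07 ± 0.23, and PIN2 (-0.07 ± 0.229) was not called.

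Shoot photosynthesis genes fell in 20 of 22 cases at 9 h in WT, with LHCB2.1 at -5.82 ± 0.515 and LHCA1 at -3.90 ± 0.366 (camera adjusted p = 2.35e-10, and adjusted p = 0.464 with an estimated correlation). Root hair genes fell in 6 of 8 cases and rose in 1, with PRP3 at -7.21 ± 1.05 and EXPA7 at -4.97 ± 0.659 (camera adjusted p = 0.0455, and adjusted p = 0.763 with an estimated correlation). Casparian strip and endodermis genes fell in 6 of 9 cases and rose in 1, with CASP1 at -2.88 ± 0.199 and CASP5 at -4.35 ± 0.427 (camera adjusted p = 0.00236, and adjusted p = 0.327 with an estimated correlation). Iron-deficiency genes fell in 9 of 10 cases, among them the ferric reductase gene FRO2 (-2.86 ± 0.26) and the iron transporter gene IRT1 (-2.48 ± 0.341), with an adjusted p = 0.291 with an estimated correlation. Cell division genes fell in 16 of 19 cases, with CYCB1-2 at -1.76 ± 0.136 and an adjusted p = 0.338 with an estimated correlation. Hypoxia-responsive genes rose in 7 of 10 cases, or 9 when adjusted over the list alone, with ADH1 at 5.88 ± 0.207 (camera adjusted p = 3.37e-08, and adjusted p = 0.0398 with an estimated correlation). Suberin genes rose in 14 of 17 cases and fell in 1, with FAR4, a fatty acyl reductase gene, at 1.89 ± 0.241 and an adjusted p = 0.765 with an estimated correlation. Jasmonate genes rose in 9 of 16 cases, with the storage protein gene VSP2 at 3.90 ± 0.462 and an adjusted p = 0.705 with an estimated correlation. ACS6 rose by 4.31 ± 0.423, BIP1, an ER chaperone gene, by 0.82 ± 0.113 and the clock gene ELF4 by 4.31 ± 0.151, and the clock gene LNK2 fell by 3.86 ± 0.113. In all, 11810 genes were called at 9 h, 6156 higher and 5654 lower. Higher genes were enriched for response to wounding (128 of 222, 65.2 expected, adjusted p = 4.01e-15) and response to salt stress (219 of 459, 135 expected, adjusted p = 7.44e-14), and lower genes for microtubule binding (84 of 146, 39.2 expected, adjusted p = 7.07e-12).

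At 24 h in WT, the lipid transfer protein gene LTP4 was at least 2290-fold higher, the sugar transporter gene SAG29 rose by 12.40 ± 0.523 and the cell wall invertase gene CWINV5 by 11.53 ± 0.496. ABA and osmotic-stress genes rose in 30 of 36 cases and fell in 2 (31 rose when adjusted over the list alone), with a median of 2.05, or 2.01 with genes at their counting bound (camera adjusted p = 1.96e-28, and adjusted p = 0.0193 with an estimated correlation). RD20 was 1720-fold higher (308 to 67900), the phosphatase gene HAI3 rose by 7.96 ± 0.251, P5CS1 by 2.38 ± 0.107 and RD29A by 2.07 ± 0.13. SLAH1, with 3 counts at 24 h, was 429-fold lower (147 to 2080), AT1G19900 fell by 7.79 ± 0.477 and SKOR fell by 5.44 ± 0.259. The potassium transporter gene HAK5 rose by 5.53 ± 0.631 and NPF7.2 by 5.51 ± 0.479, and HKT1 fell by 2.42 ± 0.371. SOS1 (0.08 ± 0.131), NHX1 (0.16 ± 0.112) and RBOHC (0.15 ± 0.154) were not called. PIN2 was not called at -0.37 ± 0.231, but was called at -0.76 (adjusted p = 0.00664) without WT 24 h replicate 2. AUX1 was called at 0.30 ± 0.114 (adjusted p = 0.0338), but not without WT 0 h replicate 2 (0.0812), WT 0 h replicate 3 (0.147) or WT 24 h replicate 1 (0.121), nor without the low-count filter (0.0507). RBOHD rose by 1.23 ± 0.277, RBOHF by 0.85 ± 0.127, APX2 by 6.67 ± 0.375 and DHAR1, dehydroascorbate reductase, by 1.65 ± 0.159, while RBOHG fell by 3.23 ± 0.241 and RBOHB fell by 2.35 ± 0.187. The intracellular auxin carrier gene PILS7 rose by 5.37 ± 0.472 and CYP79B2 by 3.57 ± 0.219, and IAA17 fell by 2.22 ± 0.233.

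Iron-deficiency genes fell in 9 of 10 cases at 24 h in WT, with the coumarin pathway gene CYP82C4 at -4.83 ± 0.364, the regulator BHLH38 at -4.79 ± 0.414, FRO2 at -4.11 ± 0.288 and IRT1 at -3.94 ± 0.372 (camera adjusted p = 1.01e-07, and adjusted p = 0.0698 with an estimated correlation). All 10 hypoxia-responsive genes rose, with ADH1 at 5.18 ± 0.201 (camera adjusted p = 3.36e-08, and adjusted p = 0.0464 with an estimated correlation). Jasmonate genes rose in 9 of 16 cases, with VSP2 at 7.03 ± 0.492 and VSP1 at 5.58 ± 0.409 (camera adjusted p = 0.0112, and adjusted p = 0.622 with an estimated correlation). ROS-scavenging enzyme genes rose in 13 of 32 cases and fell in 4 (camera adjusted p = 0.0415, and adjusted p = 0.464 with an estimated correlation). Xylem and phloem genes rose in 10 of 12 cases, with the laccase gene LAC17 at 2.06 ± 0.242 (camera adjusted p = 0.0368, and adjusted p = 0.763 with an estimated correlation). Casparian strip and endodermis genes fell in 5 of 9 cases and rose in 2, with CASP1 at -2.11 ± 0.193 (camera adjusted p = 0.0466, and adjusted p = 0.567 with an estimated correlation). Root hair genes fell in 3 of 8 cases and rose in 1, with COBL9 at -2.07 ± 0.535. EXPA7 was called at -1.44 ± 0.532 (adjusted p = 0.0305) but not by DESeq2 (adjusted p = 0.124), nor without WT 0 h replicate 1 (0.061), replicate 2 (0.0528) or replicate 3 (0.0674), nor without WT 24 h replicate 1 (0.139) or replicate 3 (0.111), and had -2.30 without WT 24 h replicate 2. The stem cell niche gene WOX5 rose by 2.82 ± 0.219 and FAR4 by 2.43 ± 0.245. In all, 10255 genes were called, 5376 higher and 4879 lower, but 5150 higher and 5339 lower in a fit of only the compared groups. Higher genes were enriched for secondary metabolic process (147 of 317, 81.2 expected, adjusted p = 2.8e-12) and response to water deprivation (157 of 376, 96.4 expected, adjusted p = 2.6e-09), and lower genes for structural constituent of ribosome (112 of 276, 64.2 expected, adjusted p = 1.56e-07).

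WT at 24 h was also compared directly with 3 h, without the 0 h libraries. No roots are labelled as untreated at either time, so changes with time on salt and with the hour of sampling cannot be told apart. ABA and osmotic-stress genes were lower at 24 h in 33 of 36 cases and higher in 2 (median -1.88, camera adjusted p = 8.15e-36, and adjusted p = 0.00861 with an estimated correlation). COR15B fell by 9.97 ± 0.359, GOLS2, for galactinol synthase, fell by 4.62 ± 0.252 and RD29A fell by 2.58 ± 0.133. The nitrate transporter gene NRT2_1 was 2460-fold higher at 24 h (682 to 20400), EXT11 was at least 221-fold higher, and HAK5 rose by 4.68 ± 0.593, CYP79B2 by 5.83 ± 0.247 and CYP79B3 by 5.03 ± 0.204. SOS1 rose by 0.77 ± 0.133, AUX1 by 1.94 ± 0.119 and the auxin efflux carrier gene PIN7 by 2.02 ± 0.115, and RBOHC fell by 1.12 ± 0.155. Clock genes fell in 16 of 22 cases and rose in 3, with FKF1 at -4.07 ± 0.164 and LHY at 3.08 ± 0.152 (adjusted p = 0.0596 with an estimated correlation). ER protein-folding genes rose in 6 of 7 cases, with CNX1 at 1.97 ± 0.136 and BIP1 at 1.41 ± 0.115 (adjusted p = 0.235 with an estimated correlation). Cell division genes rose in 13 of 19 cases, with TSO2 at 2.08 ± 0.199 (adjusted p = 0.59 with an estimated correlation), and photosynthesis genes rose in 15 of 22 (adjusted p = 0.763 with an estimated correlation). Suberin genes fell in 11 of 17 cases and rose in 3 (adjusted p = 0.763 with an estimated correlation). Root hair genes rose in 7 of 8 cases, with EXPA7 at 3.14 ± 0.648, but the list did not pass the camera test (adjusted p = 0.0599). In all, 11789 genes were called, 6387 higher and 5402 lower.

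In vamp714, the same comparisons with 0 h ask how the mutant root changed on salt medium. At 3 h, all 36 ABA and osmotic-stress genes rose (median 4.18, camera adjusted p = 5.95e-78, and adjusted p = 0.00067 with an estimated correlation), with COR15A at least 4430-fold higher, RD29A at 5.06 ± 0.149 and P5CS1 at 3.24 ± 0.111. GASA3 was at least 1370-fold higher, MYB41 rose by 5.23 ± 0.226 and ADH1 by 7.54 ± 0.223, and EXT13 was at least 408-fold lower. SLAH1 fell by 8.34 ± 0.532, HKT1 fell by 1.57 ± 0.352, SOS1 fell by 0.91 ± 0.134 and AUX1 fell by 1.69 ± 0.118. NHX1 rose by 0.67 ± 0.112, RBOHC by 0.98 ± 0.154 and RBOHF by 1.05 ± 0.128, while RBOHD (0.11 ± 0.275) and PIN2 (0.06 ± 0.23) were not called. Root hair genes fell in 7 of 8 cases, with PRP3 at -7.27 ± 1.06 and EXPA7 at -4.10 ± 0.638 (adjusted p = 0.763 with an estimated correlation), and all 10 iron-deficiency genes fell (adjusted p = 0.35 with an estimated correlation). Jasmonate genes rose in 4 of 16 cases and fell in 4, with JAZ6 at -1.86 ± 0.261. In all, 12429 genes were called, 5878 higher and 6551 lower.

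At 9 h in vamp714, 35 of 36 ABA and osmotic-stress genes rose (median 2.62, camera adjusted p = 1.19e-44, and adjusted p = 0.00709 with an estimated correlation), with RD29A at 2.61 ± 0.133 and P5CS1 at 2.35 ± 0.107. GASA3 was at least 1040-fold higher and the small heat shock protein gene ATHSP22.0 was 4620-fold higher (829 to 183000), while PRP3 was 3810-fold lower (684 to 151000), EXPA7 fell by 6.27 ± 0.772 and FRO2 fell by 3.41 ± 0.294. HKT1 fell by 2.91 ± 0.388 and AUX1 fell by 0.61 ± 0.115, and NHX1 rose by 0.44 ± 0.112 and RBOHF by 0.72 ± 0.127. RBOHD was called at 0.97 ± 0.275, but not without vamp714 9 h replicate 1 (0.61, adjusted p = 0.0625). SOS1 (-0.19 ± 0.131), RBOHC (0.20 ± 0.154) and PIN2 (-0.28 ± 0.23) were not called. Casparian strip and endodermis genes fell in 6 of 9 cases and rose in 1 (adjusted p = 0.242 with an estimated correlation), and ER protein-folding genes rose in 6 of 7 (adjusted p = 0.478 with an estimated correlation). In all, 12083 genes were called, 6236 higher and 5847 lower.

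At 24 h in vamp714, CWINV5 was 11100-fold higher (3080 to 91900), ATHSP22.0 was 12500-fold higher (2240 to 493000) and SLAH1 was at least 774-fold lower. ABA and osmotic-stress genes rose in 33 of 36 cases and fell in 1 (median 2.26, camera adjusted p = 9.26e-31, and adjusted p = 0.0134 with an estimated correlation), with RD29A at 2.32 ± 0.132 and P5CS1 at 2.07 ± 0.106. HKT1 fell by 1.96 ± 0.359 and RBOHF rose by 0.84 ± 0.127. The iron regulator gene BHLH38 was 203-fold lower (55.7 to 1680), with 8 of 10 iron-deficiency genes lower (adjusted p = 0.235 with an estimated correlation). Root hair genes fell in 7 of 8 cases and rose in 1, with EXPA7 at -4.22 ± 0.632 and COBL9 at -4.12 ± 0.608, or -6.78 and -6.91 without vamp714 24 h replicate 3 (camera adjusted p = 0.0295, and adjusted p = 0.705 with an estimated correlation). ROS-scavenging enzyme genes rose in 17 of 32 cases and fell in 5 (camera adjusted p = 0.00344, and adjusted p = 0.239 with an estimated correlation). In all, 11421 genes were called, 5880 higher and 5541 lower. RBOHC (-0.40 ± 0.155), RBOHD (0.74 ± 0.275) and PIN2 (-0.60 ± 0.231) were called, but each lost its call without at least 1 library. The adjusted p was 0.188 for RBOHC without vamp714 0 h replicate 1, 0.128 without vamp714 24 h replicate 1 and 0.112 without replicate 2. For RBOHD it was 0.0583 and 0.0843 without vamp714 0 h replicates 2 and 3, and 0.085 and 0.0609 without vamp714 24 h replicates 1 and 2. For PIN2 it was 0.0944 and 0.113 without vamp714 0 h replicates 2 and 3, and 0.07, 0.0787 and 0.0602 without vamp714 24 h replicates 1, 2 and 3. SOS1 (0.17 ± 0.131) and AUX1 (0.05 ± 0.114) were not called, and NHX1 (0.18 ± 0.112) was called only without vamp714 0 h replicate 1 (0.34, adjusted p = 0.00911).

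The direct comparison of vamp714 with WT asks which genes differ with the genotype. Over the mean of the 4 times (n = 12 libraries per genotype), a few genes were near absent in one genotype. AT5G61670, annotated as orange protein (chromosome 5, 24783429 to 24786265), had 10454 counts in WT and 5 in vamp714, a 1890-fold difference (808 to 5810). AT3G44006 was 1100-fold lower in vamp714 (305 to 9130) and the pseudogene AT4G08093 was 437-fold lower (170 to 1610). In the other direction, AT5G61720 (chromosome 5, 24801505 to 24803395) was 3190-fold higher in vamp714 (572 to 126000), and QQS, an orphan gene linked to starch content, was higher by 7.14 ± 0.147 (76 counts in WT and 9770 in vamp714). AT1G75945 was higher by 4.39 ± 0.335, AT5G35935 by 2.12 ± 0.0785 and AT3G29120 by 1.42 ± 0.105, and SOT16, a glucosinolate sulfotransferase gene, had -2.93 ± 0.0688. In all, 232 genes were called, 65 higher and 167 lower. The count was 154 without WT 0 h replicate 1 and 384 without vamp714 9 h replicate 1.

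**Figure D3:**
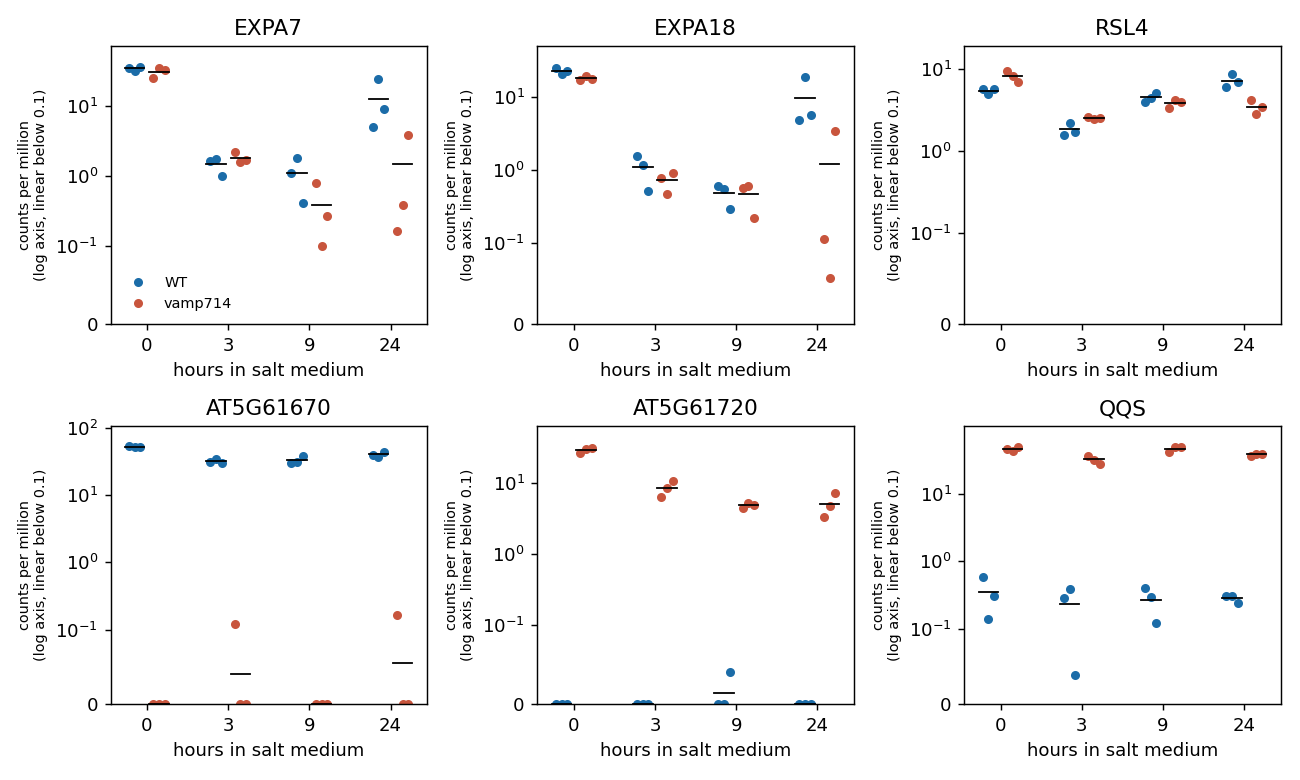
CPM (vertical axis, logarithmic and linear below 0.1) of EXPA7, EXPA18, RSL4, AT5G61670, AT5G61720 and QQS by hours in salt medium, with 1 point per library and a line at each group mean. At 24 h EXPA7 lies at 5.03, 24.3 and 9.16 CPM in WT and at 0.166, 0.392 and 3.91 CPM in vamp714.

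Genes of the iron-deficiency response were lower in vamp714 over the mean of the times, in 4 of 10 cases, also when adjusted over the list alone, with a median of -0.73 (camera adjusted p = 7.71e-15, and adjusted p = 0.0081 with an estimated correlation). The 4 genes were CYP82C4 at -1.71 ± 0.182, IRT1 at -1.39 ± 0.175, FRO2 at -1.08 ± 0.141 and F6H1, which makes coumarins that mobilise iron, at -0.85 ± 0.0912. Of 37 auxin-responsive genes, GH3.3 (-1.22 ± 0.211) and IAA30 (-0.64 ± 0.134) were lower (camera adjusted p = 0.00326, and adjusted p = 0.402 with an estimated correlation). Of 22 clock genes 4 were higher and 1 lower, with COR27 at 0.53 ± 0.0995 and CCA1 at -0.24 ± 0.0517 (camera adjusted p = 0.00212, and adjusted p = 0.444 with an estimated correlation). The superoxide dismutase gene FSD1 was higher by 0.25 ± 0.0516 and the suberin regulator MYB41 had -0.59 ± 0.0993. P5CS1 was called at 0.22 ± 0.0509, but lost its call without any one of 14 of the 24 libraries (adjusted p from 0.0523 to 0.0854), and the other 9 genes followed in every contrast were not called (-0.15 to 0.53). No member of the ion transport, NADPH oxidase, auxin transport, auxin synthesis and signalling or SNARE lists was called by edgeR, with 2455 of all tested genes at an unadjusted p under 0.05 and 452 genes called by DESeq2. Higher genes were enriched for circadian rhythm (7 of 143, 0.415 expected, adjusted p = 0.000325) and lower genes for secondary metabolic process (15 of 317, adjusted p = 8.31e-05) and glutathione transferase activity (7 of 56, 0.43 expected, adjusted p = 0.000204).

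Before salt, at 0 h, more genes differed between the genotypes than at any later time: 1006 were called, 434 higher and 572 lower in vamp714, but 762 higher and 669 lower in a fit of only the compared groups. ABA and osmotic-stress genes were lower in 11 of 36 cases and higher in 3 (14 and 4 when adjusted over the list alone), with a median of -0.35, or -0.26 with genes at their counting bound (camera adjusted p = 1.43e-05, and adjusted p = 0.478 with an estimated correlation). The phosphatase gene HAI1 had -1.34 ± 0.237 and LEA4-5, which encodes a protective late embryogenesis protein, had -1.28 ± 0.159. MYB41 had -2.07 ± 0.219, the ascorbate peroxidase gene APX1 had -0.66 ± 0.148 and the auxin repressor gene IAA28 had -0.57 ± 0.107. The small heat shock protein gene HSP17.6A was higher by 3.78 ± 0.45, JAZ1 by 0.89 ± 0.166 and the clock gene PRR5 by 0.66 ± 0.132. QQS was higher by 7.004 ± 0.281, AT5G61720 was at least 689-fold higher, AT5G61670 at least 1040-fold lower and AT4G08093 at least 179-fold lower. Of 10 iron-deficiency genes, 4 were lower, with CYP82C4 at -1.78 ± 0.299, FRO2 at -1.18 ± 0.242 and F6H1 at -0.99 ± 0.176 (camera adjusted p = 0.000187, and adjusted p = 0.239 with an estimated correlation). ROS-scavenging enzyme genes were lower in 8 of 32 cases and higher in 2 (adjusted p = 0.322 with an estimated correlation), auxin-responsive genes lower in 5 of 37 (adjusted p = 0.464 with an estimated correlation) and clock genes higher in 4 of 22 and lower in 1 (adjusted p = 0.402 with an estimated correlation). Higher genes were enriched for cellular response to hypoxia (26 of 235, 4.88 expected, adjusted p = 6.46e-09) and lower genes for response to water deprivation (38 of 376, 10.3 expected, adjusted p = 1.27e-08).

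P5CS1 was called at 0 h at 0.43 ± 0.103, but not without WT 0 h replicates 1 or 2 (adjusted p = 0.101 and 0.0512) or vamp714 0 h replicates 2 or 3 (0.0581 and 0.0717). RD29A was called at -0.44 ± 0.126, but not without WT 0 h replicates 1, 2 or 3 (0.159, 0.107 and 0.0827), vamp714 0 h replicates 2 or 3 (0.0973 and 0.189), with RLE size factors (0.0622) or without the low-count filter (0.0546). The other 8 genes followed in every contrast were not called at 0 h (-0.07 to 0.39). SOS3 of the ion transport list was called lower in vamp714 at 0 h, but not without any 1 of 4 libraries (edgeR adjusted p from 0.0553 to 0.13). PIN5 of the auxin transport list was also called lower, but not without any 1 of the 6 libraries (0.0785 to 0.238). The count of 1006 was lower in every fit with 5 of the 6 libraries: 534, 508 and 569 without WT 0 h replicates 1, 2 and 3, and 635, 631 and 643 without vamp714 0 h replicates 1, 2 and 3.

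At 3 h, iron-deficiency genes were again lower in vamp714, in 4 of 10 cases and in 6 when adjusted over the list alone (median -1.06, camera adjusted p = 2.16e-13, and adjusted p = 0.00998 with an estimated correlation). CYP82C4 had -2.27 ± 0.336, IRT1 -2.13 ± 0.351 (-1.91 and adjusted p = 0.0566 without vamp714 3 h replicate 1) and F6H1 -1.16 ± 0.186. FRO2, the other of the 4, was not called without any 1 of the 6 libraries except WT 3 h replicate 2 (adjusted p from 0.0502 to 0.0845). AT5G61670 was 891-fold lower (246 to 7370), QQS was higher by 7.19 ± 0.309 and AT5G35935 by 2.16 ± 0.157, and the cytochrome P450 gene CYP71A12 had -2.49 ± 0.394. In all, 72 genes were called, 12 higher and 60 lower, and 24 without WT 3 h replicate 1, 36 without WT 3 h replicate 2 and 30 without vamp714 3 h replicate 1. Shoot photosynthesis genes had a median of 0.81 with 0 of 22 called by edgeR (15 when adjusted over the list alone; camera adjusted p = 1.34e-07, and adjusted p = 0.571 with an estimated correlation). Their summed level was 873.8 CPM in vamp714 3 h replicate 3 and 308 to 374.9 CPM in the other 5 libraries. None of the 10 genes followed in every contrast was called at 3 h (-0.48 to 0.29), although 2507 genes had an unadjusted p under 0.05 and DESeq2 called 189 genes in all.

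At 9 h, 16 genes were called, 7 higher and 9 lower. AT5G61670 was at least 656-fold lower, QQS was higher by 7.34 ± 0.286, SOT16 had -3.08 ± 0.138 and the clock gene CCA1 had -0.74 ± 0.111 (adjusted p = 0.758 in a fit of only the compared groups). The count was 40 without WT 9 h replicate 2 and 119 without vamp714 9 h replicate 1. Jasmonate genes had a median of -0.61 with 0 of 16 called by edgeR and 7 lower when adjusted over the list alone (camera adjusted p = 4.72e-05, and adjusted p = 0.392 with an estimated correlation). None of the 10 genes followed in every contrast was called at 9 h (-0.40 to 1.53, the highest for HKT1), with 1241 genes at an unadjusted p under 0.05 and 45 called by DESeq2.

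At 24 h, root hair genes were lower in vamp714, in 4 of 8 cases and in 7 when adjusted over the list alone (median -2.47, camera adjusted p = 2.44e-10, and adjusted p = 0.114 with an estimated correlation). The regulator of hair growth RSL4 had -1.07 ± 0.18, the wall genes EXPA7 -2.94 ± 0.625, EXPA18 -2.82 ± 0.645 and LRX1 -3.05 ± 0.701. Without WT 24 h replicate 2 none of the 8 was called by edgeR: RSL4 had -0.92 (adjusted p = 0.0515), EXPA7 -2.07 (0.302), EXPA18 -1.93 (0.4) and LRX1 -2.00 (0.409). EXPA7, EXPA18 and LRX1 also lost their calls without vamp714 24 h replicate 1 (0.106, 0.138 and 0.137) or replicate 2 (0.087, 0.0959 and 0.1), and 0 of 8 were called in a fit of only the compared groups (smallest adjusted p = 0.471). With the replicate block EXPA18 (adjusted p = 0.065) and LRX1 (adjusted p = 0.0829) were not called. Other omissions gave more calls: 6 of 8 without WT 24 h replicate 1, 5 without replicate 3, and 7 without vamp714 24 h replicate 3 (EXPA7 -5.50, EXPA18 -6.75, LRX1 -7.35). With WT 24 h replicate 2 and vamp714 24 h replicate 3 both removed, 6 were called (median -4.36), but RSL4 was not (-0.91, adjusted p = 0.0613). Extensins and other wall proteins gave the GO term structural constituent of cell wall 12 lower genes of 28 (0.165 expected, adjusted p = 1.01e-16). This GO test used the same calls at 24 h and was not repeated without WT 24 h replicate 2, so it gives no separate support for the root hair genes. AT5G61670 was 854-fold lower (292 to 4150), QQS was higher by 7.04 ± 0.299 and AT3G29120 by 1.45 ± 0.216, and the auxin repressor gene IAA30 had -1.61 ± 0.299. In a fit of only the compared groups AT3G29120 and IAA30 were not called (adjusted p = 0.415 and 0.688). In all, 159 genes were called, 29 higher and 130 lower, but 294 without WT 24 h replicate 1, 38 without WT 24 h replicate 2, 68 without vamp714 24 h replicate 1 and 9 in a fit of only the compared groups. None of the 10 genes followed in every contrast was called at 24 h (-0.43 to 0.39), with 2747 genes at an unadjusted p under 0.05 and 395 called by DESeq2.

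Whether the change on salt medium differed between the genotypes was tested with the interaction of genotype and time against 0 h. The ABA-responsive gene LEA4-5 and the suberin regulator MYB41, both lower in vamp714 at 0 h, had a more positive change in vamp714 at 3 h (1.36 ± 0.214 and 1.94 ± 0.282), 9 h (1.49 ± 0.215 and 1.95 ± 0.286) and 24 h (1.29 ± 0.215 and 2.04 ± 0.305). HSP17.6A, higher in vamp714 at 0 h, had -4.03 ± 0.534 at 3 h and -3.65 ± 0.526 at 9 h. The differences of LEA4-5, MYB41 and HSP17.6A at 0 h were of similar size and opposite sign. Their values here carry that offset and do not by themselves show a different response to salt. ABA and osmotic-stress genes had a more positive change in vamp714 in 5 of 36 cases at 3 h, 6 at 9 h and 7 at 24 h (camera adjusted p = 0.00268, 2.54e-08 and 4.72e-05, and adjusted p = 0.701, 0.338 and 0.513 with an estimated correlation). Jasmonate genes had a more negative change in 2 of 16 cases at 3 h, 4 at 9 h and 1 at 24 h (adjusted p = 0.464, 0.242 and 0.523 with an estimated correlation). The root hair list had a median of -2.27 at 24 h with 1 of 8 called, RSL4 at -1.67 ± 0.25, and 7 lower when adjusted over the list alone (adjusted p = 0.239 with an estimated correlation). RSL4 stood higher in vamp714 at 0 h (9.61, 8.29 and 6.98 CPM, against 5.65, 5.01 and 5.76 in WT), and this offset is part of its value. Genes with a more negative change at 3 h were enriched for response to hypoxia (26 of 260, adjusted p = 8.35e-10) and those with a more positive change for sequestering of iron ion (5 of 12, adjusted p = 7.6e-05).

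The change from 0 h differed in 554 genes at 3 h, 282 at 9 h, 329 at 24 h and 395 in a joint test of the 3 times. All these tests use the 0 h libraries, and a joint test of the genotype by time difference without them called 7 genes, each also among the 395. Single libraries moved the counts. At 3 h the count was 219 and 261 without WT 0 h replicates 2 and 3, 348 and 312 without vamp714 0 h replicates 1 and 2, 219 and 231 without WT 3 h replicates 1 and 2, and 244 without vamp714 3 h replicate 1. At 9 h it was 128, 141 and 179 without WT 0 h replicates 1, 2 and 3, 158 and 134 without vamp714 0 h replicates 2 and 3, 151 and 461 without WT 9 h replicates 1 and 2, and 572, 118 and 127 without vamp714 9 h replicates 1, 2 and 3. At 24 h it was 199 and 190 without WT 0 h replicates 1 and 2, 202 without vamp714 0 h replicate 2 and 539 without vamp714 24 h replicate 3. In the joint test it was 215, 196 and 243 without WT 0 h replicates 1, 2 and 3, 237 and 253 without vamp714 0 h replicates 2 and 3, 250 and 233 without WT 3 h replicates 1 and 2, 616 without vamp714 9 h replicate 1 and 702 without vamp714 24 h replicate 3.

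**Figure D4:**
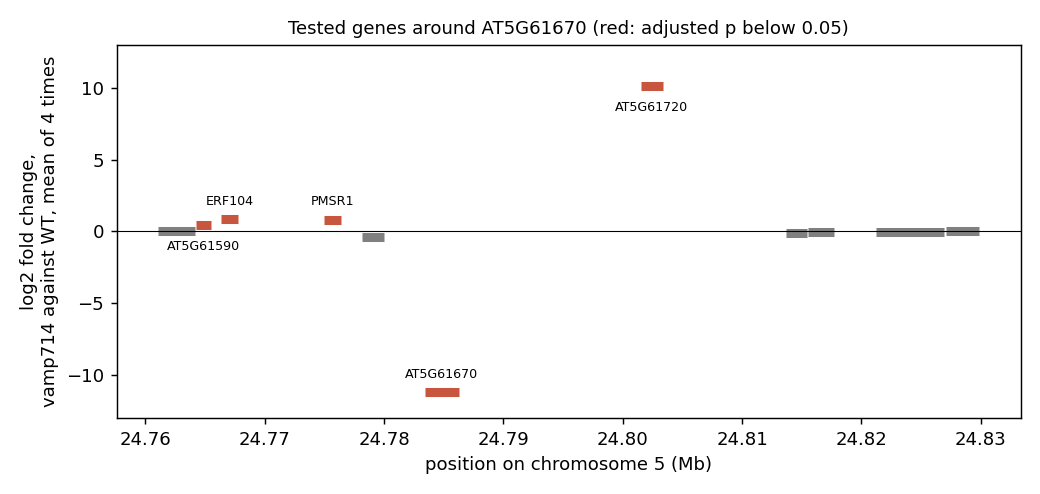
Log2 fold change of vamp714 against WT over the mean of 4 times (vertical axis) for tested genes along chromosome 5 around AT5G61670 (horizontal axis, Mb), with called genes in red and others in grey. AT5G61670 lies at 24783429 to 24786265 below the zero line and AT5G61720 at 24801505 to 24803395 above it, and their plotted values depend on the prior count.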

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

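The tests of other splits of the libraries and of a single vamp714 0 h library were chosen before their results were seen, while the tests of splits that kept the 0 h labels, of the hour of sampling, of single libraries at 24 h, of another part of the root and of gene positions were chosen after the result was seen.

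The difference between genotypes in the change from 0 h stood out in 554 genes at 3 h, 282 at 9 h, 329 at 24 h and 395 jointly. When the genotype labels were permuted within each time, 1 of 40 splits, the real one, reached each of these counts, and the highest other counts were 445, 206, 316 and 243. A share of 1 in 40 is the lowest these splits can give, and it concerns the labels of all times together, not the labels at 3, 9 and 24 h alone. The 4 other splits that kept the 0 h labels called 127 to 445, 76 to 206, 110 to 316 and 88 to 243 genes, and the 35 that mixed them at most 1. The counts thus depend on the 0 h labels and do not by themselves show a different response to salt. They were also lower where the later labels were mixed. Of the 4 splits that kept the 0 h labels, the one with the highest counts also kept the genotypes apart at 1 later time. The others did so at no later time and called 127 to 206, 76 to 153, 110 to 183 and 88 to 160 genes. No split but the real one did so at more than 1 later time, so the share of the 0 h labels cannot be separated. Leaving out 1 library at a time gave 219 to 471 genes at 3 h, 118 to 572 at 9 h, 190 to 539 at 24 h and 196 to 702 jointly.

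At 3 h, the change in vamp714 less that in WT -4.03 for HSP17.6A, 1.36 for LEA4-5, 1.497 for HAI1, -0.74 for the clock gene PRR7, -1.17 for JAZ1, 1.94 for MYB41 and -2.35 for APX2. At 9 h, NAS2, which makes the metal chelator nicotianamine, had 3.36, the cytokinin response regulator gene ARR7 2.42, HSP17.6A -3.65, LEA4-5 1.49, the transcription factor gene RD26 1.103, the jasmonate synthesis gene LOX3 -6.07, CCA1 -0.87 and MYB41 1.95. At 24 h, NAS2 had 3.73, MYB102 2.86, the extensin gene EXT10 -4.89, AT3G54580 -4.53, RSL4 -1.67, LEA4-5 1.29, MYB41 2.04 and GR1, glutathione reductase, 0.61. HSP17.6A, LEA4-5, HAI1, JAZ1 and MYB41 differed between the genotypes in the opposite direction at 0 h, and that offset is part of their values. APX2 was not called without any 1 of the 12 libraries compared except vamp714 0 h replicate 3, WT 3 h replicate 3 and vamp714 3 h replicate 2 (adjusted p from 0.0518 to 0.128). LOX3 was not called without any 1 of the 6 libraries at 0 h, WT 9 h replicate 3 or vamp714 9 h replicates 2 and 3 (0.0636 to 0.119). It also lost its call in a fit of only the compared groups (0.174), with the replicate block (0.0683) and with the 2 libraries at 24 h removed (0.0547). PRR7 was not called without WT 0 h replicates 2 or 3, vamp714 0 h replicate 1, WT 3 h replicates 1 or 2, or vamp714 3 h replicate 1 (0.0617 to 0.0816). GR1 was not called without any WT 0 h replicate, vamp714 0 h replicates 1 or 3, or WT 24 h replicates 2 or 3 (0.0529 to 0.0722), in a fit of only the compared groups (0.0945) or with the 2 libraries at 24 h removed (0.0961), and ARR7 not without vamp714 0 h replicate 3 (0.0503). EXT10 was not called by DESeq2 (0.0643), and had -10.53 without vamp714 24 h replicate 3 and -3.67 without WT 24 h replicate 2.

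The first pattern is that 1006 genes differed between the genotypes at 0 h and 159 at most later. Without vamp714 0 h replicate 1, which correlated with the other vamp714 0 h libraries at r = 0.984 and 0.981 where those correlated at 0.991 across genes, 635 genes were still called, which argues against that library as the whole cause. A different hour of sampling remains open: 5 of 22 clock genes were called, over the 1.04 that the overall share gives, and circadian rhythm was enriched among higher genes (14 of 143, 2.97 expected, adjusted p = 0.000615). The 10 splits of the 6 libraries are too few for a share under 0.05 (1006 genes in the real split, 0 in the highest other). A difference between the genotypes before salt is a candidate explanation, and the series holds no further 0 h samples to test it.

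The second pattern is the lower level of root hair genes in vamp714 at 24 h (median -2.47, members from -3.05 to 0.07). Without vamp714 24 h replicate 3 the median was -5.21, with 7 of 8 called, so that library did not cause the pattern. WT 24 h replicate 2 remains open: without it the median was -1.59, members ran from -2.07 to 0.22 and 0 of 8 were called by edgeR (smallest adjusted p = 0.0515) as the difference shrank and 5 libraries remained. With both libraries left out the median was -4.36 with 6 of 8 called, which goes against it, but that fit also drops the vamp714 library closest to WT (EXPA7 at 3.91 CPM, against 0.166 and 0.392 in the others). Another part of the root in some samples is also a candidate explanation, since xylem and phloem genes were lower by camera (adjusted p = 0.0455, and adjusted p = 0.765 with an estimated correlation), although 0 of 12 were called by edgeR, and an effect of the genotype on root hairs stays open beside them.

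The third pattern is the set of genes near absent in one genotype over the 4 times together. The rule, set after the data were seen, asked for under 2% of the level in the other genotype, which had at least 1 CPM. It pooled the 12 libraries of each genotype and did not ask for the same difference in every library. QQS, AT3G44006 and FAMT lie on chromosome 3, TAT3 and AT2G08735 on chromosome 2 and AT4G08093 on chromosome 4. FAMT had 2175 counts in WT and 30 in vamp714, TAT3 2083 and 28, and AT2G08735 347 and 1. AT5G61670 and AT5G61720 both lie on chromosome 5. A 50 kb window there held 5 of 231 called genes of the genotype contrast (permutation p = 8e-04), but 2 of the 5 prompted the test. Without them no window held more than 3, the median of 10000 random draws (permutation p = 0.722). The 3 called genes left near AT5G61670 could not exceed that median, so the second test cannot decide about this window. The others in it were PMSR1 at 0.80, ERF104 at 0.84 and AT5G61590 at 0.45, which were named after their values were seen, and AT5G61590 lost its call without any 1 of 17 libraries (adjusted p from 0.0586 to 0.0777) or with the 2 libraries at 24 h removed (0.0975). A second change of the DNA in the vamp714 line away from VAMP714, such as a further insertion or a segment from another accession, therefore stays open. Called genes did not crowd within 1 Mb of VAMP714, with 3 there where 4.61 were expected (permutation p = 0.844). AT5G61670 and AT5G61720 lie outside that stretch, so the count cannot decide whether DNA linked to VAMP714 further away accounts for them. An effect of VAMP714 itself on the near-absent genes was not tested, since the series holds 1 mutant line.

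The other comparisons of 3 against 3 libraries also had 10 splits, too few for a share under 0.05. The salt comparisons and WT at 24 h against 3 h called 10255 to 13667 genes in the real split and at most 2 in another. Between genotypes, the real and highest other counts were 72 and 1 at 3 h and 159 and 91 at 24 h. At 9 h the real split called 16 genes and 3 of 10 splits called as many, the highest 718, which points to a structure of the samples. The splits with 718 and 350 genes set vamp714 replicate 1 beside WT replicate 1 and another WT library, while the split with WT replicates 2 and 3 beside it called 0. Over the mean of the times, 1 of 40 permuted splits, the real one, reached 232 genes. The 4 other splits that kept the 0 h labels called 1 to 164 genes, and the 35 that mixed them at most 1. The share of 1 in 40 thus concerns the labels of all times together, and 4 splits are too few to judge the labels at 3, 9 and 24 h alone.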

How the results depend on the processing

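Removal of WT 24 h replicate 2 with vamp714 24 h replicate 3 and the joint test without 0 h libraries were chosen after seeing the data, and the other settings before. Counts within 1.5 times of the reported ones are not repeated here. Of 351 gene values chosen for naming (141 genes, 282 called), no called value changed direction in any setting. DESeq2 kept 348 of 350 in both direction and side of the threshold, RLE size factors 349 of 351, no low-count filter 348, the stricter filter 351, the replicate block 346, the compared groups alone 296 of 307, the 2 libraries removed 338 of 351, and omission of each library 2784 of 3000. With RLE size factors 108 of 110 list calls held, and with the block 104. With the block LRX1 and EXPA18 between genotypes at 24 h (adjusted p = 0.0829 and 0.065) and LOX3 in the interaction at 9 h (0.0683) were not called. A rule that every pair of libraries with the same number exceeds r = 0.1 across genes was not met. Of 84 pairs 18 did (r from -0.161 to 0.529, median 0.0182, highest for replicate 1 of both genotypes at 9 h). That rule is strict, so missing it does not exclude a link between some libraries of the same number. As a hint of such a link, 15 of 24 libraries were closest to their own number, and the main model held no term for it. Narrower GO size limits left 1309 of 2172 terms past the threshold, against 1570 of 3495. Depth of 16696442 to 29943561 counts limits genes with few counts, whose folds are given as bounds or with a counting interval.

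Requiring a 2-fold change as well, which by construction removes genes, left 6409, 5505 and 4424 genes in WT at 3, 9 and 24 h, 5930, 5722 and 5117 in vamp714, 4979 in WT at 24 h against 3 h, 302 and 45 between genotypes at 0 h and 3 h, 60 over the mean of times, and 260, 173 and 189 in the interactions. DESeq2 called 189, 45 and 395 genes between genotypes at 3, 9 and 24 h, 452 over the mean, and 1188, 536, 620 and 1348 in the interactions at 3, 9 and 24 h and jointly; the cause was not tested. A fit of only the compared groups, with fewer libraries to estimate the spread, called 158, 9 and 9 genes between genotypes at 3, 9 and 24 h, and 1492 and 169 in the interactions at 3 h and 9 h. With the 2 libraries removed, 135 genes were called between genotypes at 3 h, and 1194, 482 and 734 in the interactions at 3 h, 9 h and jointly; the cause was not tested. Without the 0 h libraries the joint test called 7. With an estimated correlation 11 list calls were left, and with fry 79 of the 110 held.

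Leaving out 1 library at a time gave 12562 to 12926, 10558 to 11061 and 8703 to 10084 genes in WT at 3, 9 and 24 h, 11253 to 11652, 10962 to 11363 and 10436 to 11044 in vamp714, and 10563 to 10952 in WT at 24 h against 3 h. Between genotypes it gave 508 to 643, 24 to 70, 13 to 119 and 38 to 294 at 0, 3, 9 and 24 h and 154 to 384 over the mean, and in the interactions 219 to 471, 118 to 572, 190 to 539 and 196 to 702.

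Values that changed sign were all of genes not called. With the 2 libraries removed these were RBOHF (-0.12), PIN2 (0.10) and AUX1 (0.037) between genotypes at 24 h, and RBOHF (-0.022) and RIN1 (0.018) over the mean. Leaving out 1 library gave ranges across 0, whose cause was not tested. In WT these were PIN2 -0.185 to 0.064 at 3 h, SOS1 -0.056 to 0.123 and PIN2 -0.185 to 0.114 at 9 h, and SOS1 -0.085 to 0.194 at 24 h. In vamp714 they were PIN2 -0.089 to 0.154 at 3 h, RBOHC -0.014 to 0.33 at 9 h and AUX1 -0.028 to 0.165 at 24 h. Between genotypes at 0 h they were SOS1 -0.017 to 0.227, HKT1 -0.161 to 0.012, NHX1 -0.074 to 0.214, RBOHC -0.022 to 0.184, RBOHF -0.049 to 0.204 and PIN2 -0.138 to 0.11. At 3 h they were PIN2 -0.05 to 0.207 and RD29A -0.105 to 0.01. At 9 h they were RBOHC -0.318 to 0.033, RBOHD -0.757 to 0.112, RBOHF -0.054 to 0.124, AUX1 -0.037 to 0.12 and P5CS1 -0.03 to 0.108. At 24 h they were RBOHD -0.211 to 0.023, RBOHF -0.075 to 0.206, PIN2 -0.531 to 0.119 and AUX1 -0.128 to 0.051. Over the mean they were NHX1 -0.008 to 0.064, RBOHF -0.011 to 0.059 and RIN1 -0.028 to 0.021.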

Other observations

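The GO tests were planned, while the terms named here, the joint test without 0 h libraries and the comparison with the authors' columns were chosen after the result was seen.

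Genes with a more positive change from 0 h in vamp714 than in WT were enriched for the GO term cytokinin-activated signaling pathway, with 7 of 52 members called at each of 3 h (0.471 expected, adjusted p = 0.000296), 9 h (adjusted p = 0.000395) and 24 h (adjusted p = 0.000913). Response to water deprivation had 15 of 376 members called at 3 h (3.41 expected), 17 at 9 h (3.3 expected, adjusted p = 8.32e-05) and 15 at 24 h (adjusted p = 0.0011). Genes with a more negative change were enriched for response to hydrogen peroxide, with 10 of 74 members called at 3 h (adjusted p = 0.000209), 6 at 9 h (adjusted p = 0.000571) and 7 at 24 h (adjusted p = 0.00054). These tests share the 0 h libraries and do not separate a difference before salt from one on salt. At 0 h, 10 of the 74 hydrogen peroxide genes were called higher in vamp714 (1.54 expected, adjusted p = 0.000863).

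Before salt, genes called lower in vamp714 were enriched for mitochondrial respiratory chain, with 16 of 97 members (2.66 expected, adjusted p = 7.19e-06) and response to metal ion, with 26 of 190 (5.2 expected, adjusted p = 1.72e-08). In WT at 3 h, 69 of these 97 genes were lower than at 0 h (33.7 expected, adjusted p = 8.52e-11). At 24 h, 11 of 28 genes of structural constituent of cell wall had a more negative change in vamp714 than in WT (0.199 expected, adjusted p = 1.05e-13).

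The 7 genes of the joint test without 0 h libraries, named after their values were seen, were SOT16 (edgeR adjusted p = 1.22e-06), AT4G33930 (0.0198), AT3G28550, an extensin-like gene (0.0264), SAG13 (0.0264), AT2G14900 (0.0264), BXL1, for beta-xylosidase (0.0315), and AT3G09440, for a heat shock protein (0.0499). SOT16 had 55 to 57.1 CPM in the WT libraries at 3 h, 113 to 160 at 9 h and 277 to 376 at 24 h. In the vamp714 libraries it had 11.8 to 14.4, 14.4 to 16.7 and 12.9 to 14.6 CPM.

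The deposited log2 fold changes of the authors correlated with those computed here across genes at r = 0.995 to 0.999, where genes are not independent replicates. The authors' adjusted p was under 0.05 for 14361, 11124 and 10147 genes in WT at 3, 9 and 24 h, for 11805, 11048 and 9436 in vamp714, and for 1916, 692, 33 and 89 between genotypes at 0, 3, 9 and 24 h, with 1039 higher and 877 lower at 0 h.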
